A study of Mus musculus with 3 samples.

How the data were processed

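The values are, per the labels, single-cell 3′ tag libraries made with the 10x Chromium v3 kit, 1 library for each of 3 groups of mouse retinas at P26: wild type (WT), Tspan12 knockout (KO), and Tspan12 KO given F4L5.13. The submitters' processing notes name the genome build mm10 and Partek 9.0, without saying in which step each was used. The tables as deposited hold estimated counts per gene and cell barcode, not scaled by cell, a reading taken from the values themselves: most are whole and the rest fractional, as a quantifier that divides ambiguous reads between genes gives. The step of the submitters' processing that made them, and whether it collapsed reads to molecules, is not given in the sources used here. Of the nonzero values, 2.39% (WT), 2.33% (KO) and 2.34% (treated) lay more than 0.001 from a whole number. All values were rounded to whole numbers before use, which set 3.39%, 3.33% and 3.37% of the nonzero values, those below 0.5, to 0. In genes detected in few barcodes, 56.3%, 55.4% and 51.4% of nonzero values up to 10 were 1, a lower proportion than molecule counts would give. The values were therefore taken as reads that had not been collapsed to molecules, and they are called reads here, although the plan had assumed molecules. To keep the counting intervals from being too narrow, reads were divided by 2.66, 2.69 and 2.95 in the WT, KO and treated libraries. Each divisor is the sum of the squared values over the sum of the values in those genes, without values above 10. Leaving out the larger values lowers the divisors, so intervals are narrower and minimums easier to meet than with all values. The resulting molecule equivalents were used for every interval and every minimum. Intervals and detection limits cover counting error only and say nothing of differences between animals or dissociations.

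The marker lists, the gene lists, the rule for naming genes, the thresholds, the comparisons and all alternatives not identified as later ones were chosen before the data were examined. Barcodes with fewer than 500 detected genes or more than 20% mitochondrial reads were left out. Doublets were to be called with Scrublet, but its automatic threshold called none in the KO and treated libraries. Barcodes were instead ranked by the proportion of simulated doublets (2 per barcode, 30 principal components) among their neighbours, and the highest-ranked were left out, to the proportion expected from the number of barcodes (4.87%, 8.58% and 7.73%). That substitution was made after the data were seen.

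Kept barcodes of the 3 libraries were scaled to 10000 reads, log-transformed and clustered together on 2000 variable genes and 40 principal components, with no batch correction, since library and group are the same thing here. Leiden clustering (resolution 1.0, sub-clusters at 0.5) ran on a shared-neighbour graph of 15 neighbours with Jaccard weights. A cluster received a class name when at least 3 markers of that class were at least 2-fold above the other clusters and present in at least 20% of its cells, and when its 10 leading genes did not contradict the name. The markers covered 19 cell types, and the finer points of the naming were settled after the clusters were seen. Classes are named after the cell type whose markers they carry, and carry no other evidence of identity. A cluster with all 12 endothelial markers stayed unnamed because its 10 leading genes held 3 haemoglobin genes and fewer members of the fixed endothelial marker list, although the other 7 are also leading genes of a named endothelial cluster. Clusters without 3 markers, and all other unnamed barcodes, were left out of the comparisons.

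Within a class, reads were summed per library and scaled to CPM by all reads of that class. Ratios are CPM ratios with an exact conditional binomial 95% interval, shares have exact (Clopper-Pearson) 95% intervals, and CPM values have exact Poisson intervals. Comparisons needed at least 50 cells of the class in each library, except the planned endothelial comparison of the treated and WT libraries. With 1 library per group there is no test between groups, and none was made from cells. A gene without reads in 1 library has a limit of 3 molecule equivalents per library, from which folds are given as at least a value.

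Genes named by size met a fixed rule: a ratio of at least 2 in either direction, at least 30 molecule equivalents in the higher library, and an interval bound nearest 1 beyond 1.5. The 12 highest and 12 lowest ratios were named for Müller and endothelial cells, and the 5 highest and 5 lowest for other classes. Other genes that met the rule, among them most of those for the treated against WT comparison in classes other than Müller and endothelial cells, are not reported here. The order used a prior count of 0.5. Mitochondrial, ribosomal protein and haemoglobin genes, photoreceptor markers, crystallins, sex-linked transcripts and unnamed gene models were left out of the ranking. For each of the 20 fixed gene lists, the median log2 ratio was taken over members with at least 10 molecule equivalents in the pair of libraries, with a binomial order-statistic interval over members. Its position among 10000 random lists of equal size, matched in 20 bins of expression, is given as a percentile that describes these libraries. In each list the 4 members with most reads and the 2 highest and 2 lowest ratios could be named, and Tspan12, Fzd4, Lrp5 and Ndp always.

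On simulated data with 200 altered genes, the intervals covered the true ratio for 95.3% and 95.2% of genes in the Müller comparisons of KO against WT and of treated against KO, and for 96.5% in endothelial cells. All genes set to 3-fold met the naming rule in Müller cells and 60.0% did in endothelial cells. Of genes set to a ratio of 0.333, 98.0% and 94.0% met it in the Müller comparisons and 30.0% in endothelial cells. Of unaltered genes, 0 of 17908 and 1 of 17523 met it in the Müller comparisons and 5 of 12186 in endothelial cells. The simulation drew the same counting error that the intervals assume, without spread between cells or libraries. These rates therefore check the computation and do not give the error rate of the genes named below.

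Alternatives to the gene minimum, the mitochondrial limit, the doublet step, the clustering, the scaling (edgeR TMM and DESeq2 size factors), free RNA, depth per cell and list minimums were run one at a time. The software was Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, python-igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.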

Results

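Mouse retinas at P26 were dissociated and profiled by single-cell RNA sequencing in 3 groups: WT, Tspan12 KO, and Tspan12 KO treated with F4L5.13. TSPAN12 is the tetraspanin co-receptor that helps Norrin (Ndp) signal through FZD4 and LRP5 to β-catenin in retinal endothelial cells, and its loss leaves the deep retina without a normal vascular bed. F4L5.13 is an antibody that brings FZD4 and LRP5 together and thereby switches on the pathway without ligand. Per the labels' protocols it was injected intraperitoneally at 10 mg/kg on P6, P9 and P12 and at 4 mg/kg every 3 days from then on. The same protocols state that photoreceptors and dying cells were depleted with beads against CD73 and Annexin V, so the class shares describe the depleted suspension and not the retina. Each group has 1 library and no replicate, so every difference below is between single libraries.

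The WT, KO and treated libraries held 6092, 10769 and 9835 barcodes with values for 24071 genes. Median reads per barcode were 14797, 7351 and 6588, and the shallowest barcode had 2874 reads in the WT library but 558 and 468 in the KO and treated libraries. After filtering, 5784, 9319 and 8171 cells were kept. The gap in depth came largely from rods, which made up 4.46% of kept WT cells but 40.4% and 42.7% of KO and treated cells, so shares of other classes are given among named cells that were not photoreceptors (4737, 4525 and 3710 cells).

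Which cell classes the 3 libraries contained was examined first. Endothelial cells were the class most unequal between libraries: they were present in the WT library, no KO cell was named endothelial, and the treated library held a low share. Amacrine cells and microglia had higher shares in the KO library than in the other libraries. Endothelial cells numbered 105, or 2.22% (95% interval 1.82 to 2.68%), in WT, 0 in KO, which allows a share of up to 0.0663% by a limit of 3 counts (exact 95% bound 0.0815%), and 17, or 0.458% (0.267 to 0.733%), in treated. Their median depth was 68602 reads in WT and 73863 in treated. A further cluster of 11, 6 and 20 cells, taken as a whole, carried all 12 endothelial markers together with haemoglobin transcripts and was not counted. Haemoglobin also made up 2.71% and 0.197% of reads in the counted WT and treated endothelial cells. The 6 KO cells of that cluster each had reads from only some of the markers, a median of 5.5, except for 1 cell with all 12. With that cluster the share was 0.132% in KO and 0.992% in treated. Without any clustering, 130 WT, 2 KO and 41 treated barcodes had reads from at least 8 of the 12 endothelial markers. The deeper of these KO barcodes (37325 reads) held 52 reads of Plvap, the gene of the fenestral diaphragm. It held 4 reads of the tight-junction gene Cldn5, and also 139 of Rgs5 and 22 of Pdgfrb, both mural markers. The other KO barcode, with 6352 reads, held 85 of Cldn5 and 0 of Plvap. Mural cells, which wrap the same vessels, numbered only 4, 12 and 6, with shares of 0.0844% (0.0230 to 0.216%), 0.265% (0.137 to 0.463%) and 0.162% (0.0594 to 0.352%).

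Amacrine cells, the inhibitory interneurons of the inner retina, made up 2.49% of the named non-photoreceptor cells in WT (118 cells), 26.8% in KO (1214 cells) and 3.80% in treated (141 cells). Bipolar cells made up 57.4%, 39.8% and 61.2%, and Müller glia 35.5%, 28.5% and 30.2%. Because 1 large class lowers the shares of all others, numbers per 100 Müller cells are also given. These were 7.01, 94.2 and 12.6 for amacrine cells and 162, 139.7 and 203 for bipolar cells. Microglia were 0.296% (0.162 to 0.495%) in WT, 1.64% (1.29 to 2.05%) in KO and 0.916% (0.635 to 1.28%) in treated, or 0.831, 5.74 and 3.04 per 100 Müller cells. Horizontal cells were 0.866%, 1.79% and 2.59%, astrocytes 1.03%, 0.575% and 0.593%, and ganglion cells numbered 2, 28 and 4. Median reads per Müller cell were 19432, 27658 and 23898, and per amacrine cell 14701.5, 16743 and 20209. No comparison of expression was made in microglia, mural cells, astrocytes, ganglion cells or horizontal cells, and the lists for microglial activation, microglial homeostasis and pericyte contractile and matrix genes were not run, since a library held fewer than 50 cells of the class.

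**Figure D1:**
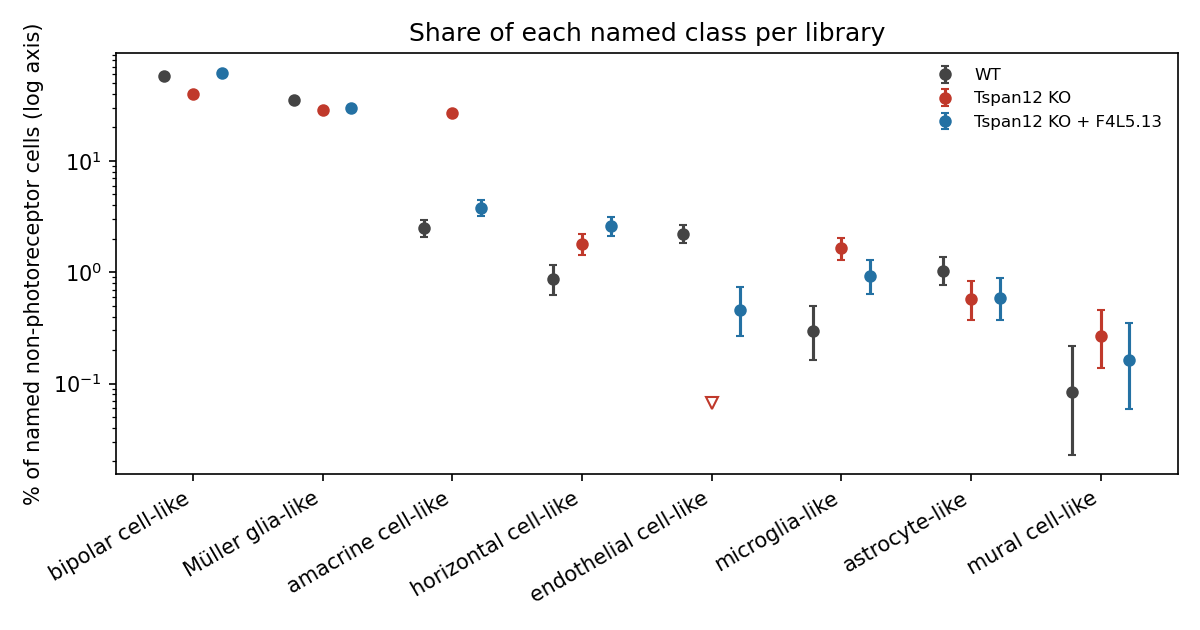
Share of each class among named non-photoreceptor cells of the WT, KO and treated libraries (log axis, percent, bars are exact 95% intervals of counting error). The open triangle marks the limit of 3 counts for the 0 endothelial cells of the KO library, 0.0663%, against 2.22% in WT and 0.458% in treated.

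The genotype was looked at through the transcripts of Tspan12 and its partners (GRCm38 positions: Tspan12, chromosome 6, 21771391 to 21879596; Fzd4, chromosome 7, 89404366 to 89410110; Lrp5, chromosome 19, 3584825 to 3686585; Ndp, chromosome X, 16885521 to 16911774). Tspan12 reads were present in all 3 libraries: 27.6 CPM (25.98 to 29.2) in WT, 17.9 CPM (16.7 to 19.2) in KO and 14.6 CPM (13.3 to 15.9) in treated over all kept cells. The part of the gene that the knockout allele deletes is not given in the sources used here, and a 3′ tag outside it checks nothing, so reads in a KO library do not contradict the label. In Müller cells Tspan12 stood at 43.8, 30.1 and 24.9 CPM, against 0.506, 1.13 and 0.989 CPM in bipolar cells, a class taken as background. In endothelial cells it was 94.3 CPM (83.3 to 106) in WT and 92.1 CPM (64.6 to 130) in treated. The receptor Fzd4 was an endothelial transcript, with 165 and 178 CPM in WT and treated endothelial cells against 3.30, 2.65 and 3.33 CPM in Müller cells. The co-receptor Lrp5 stood at 37.8 and 45.6 CPM in those endothelial cells and at 13.04, 10.00 and 16.1 CPM in Müller cells. The ligand Ndp stood at 25.0, 38.3 and 29.8 CPM in Müller cells and at 79.9, 53.8 and 58.6 CPM in the few horizontal cells, and had 1.34 CPM in WT endothelial cells and 0 reads in treated ones.

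Müller glia of the KO and WT libraries were compared to see what the glia that ensheath retinal vessels and neurons express in the library labelled Tspan12 KO. The fixed list of gliosis genes was higher in the KO library, as were genes induced by low oxygen and by interferon. Lists of β-catenin targets and of Müller homeostasis genes had negative medians, which over the alternative settings ran from −0.74 to 0.02 and from −0.35 to −0.03. The median of all genes was −0.02 (log2), so the lists below are not shifted by scaling. The cells did not all come from the same clusters, since most WT Müller cells lay in one cluster (1257 WT, 25 KO and 600 treated cells) and most KO Müller cells in another (23, 731 and 99). These comparisons therefore span distinct states of the class. Some smaller Müller clusters also carried photoreceptor markers. One with 1 WT, 150 KO and 6 treated cells had 8 cone markers, and one with 25, 4 and 75 cells had 7. Another, with 42, 11 and 27 cells, had 9 rod markers. Their median reads per cell were 43274, 51442.5 and 62093.5. Whether they held mixed barcodes was not tested.

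The fixed list of gliosis genes had a median log2 ratio of 1.41 (0.95 to 3.61), with 20 of 22 members higher in the KO library, above all of 10000 random lists (percentile 100). Gfap, the intermediate filament of reactive glia and also an astrocyte marker, stood at 15.1 CPM in WT and 256 CPM in KO, a ratio of 17.0 (14.9 to 19.6). Timp1, an inhibitor of matrix metalloproteinases, had a ratio of 30.6 (18.4 to 51.5). Bcl3, an IκB-family co-regulator of NF-κB, had one of 28.2 (10.0 to 98.7). A2m, a protease inhibitor of the acute phase, stood at 2.01 and 49.1 CPM, and Edn2, the endothelin that photoreceptor injury is known to induce in the retina, at 0.284 and 6.22 CPM. Abundant members differed little: the ratio was 1.15 for vimentin (Vim), 1.26 for ceruloplasmin (Cp) and 1.13 for Cebpd, whose log2 ratio was −0.20 in the most evenly shared cluster. Socs3, the feedback inhibitor of STAT3, was lower at a ratio of 0.900 (0.872 to 0.928), and the endothelin receptor Ednrb at 0.593 (0.492 to 0.715).

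Hypoxia-response genes had a median of 0.64 (0.19 to 0.90), with 23 of 26 members higher (percentile 100). Adm, which encodes the vasodilator adrenomedullin, stood at 2.27 CPM in WT and 132 CPM in KO, a ratio of 58.0 (41.2 to 84.5), with reads in 624 of the 1289 KO cells. Egln3, a prolyl hydroxylase that is itself a HIF target, had a ratio of 5.64 (3.71 to 8.53). The glycolytic genes Aldoa, Tpi1 and Eno1 were higher by ratios of 1.74, 1.86 and 1.64, whereas Egln1 and Pgam1 lay at 0.959 and 0.848 with intervals that include 1. Interferon-response genes were higher without exception, 14 of 14, with a median of 1.01 (0.68 to 1.91). Among them the antiviral Ifit1 stood at 11.1 and 64.1 CPM, the receptor-transporting protein gene Rtp4 at 2.68 and 15.4 CPM, and Ifitm3, which blocks viral entry, at 162 and 399 CPM.

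The β-catenin target list had a median of −0.65 (−1.02 to 0.15), with 8 of 12 measured members lower (percentile 0.0300). Lef1, the transcription factor partner of β-catenin, stood at 6.92 CPM in WT and 3.03 in KO (ratio 0.439, 0.298 to 0.625). The negative-feedback genes Nkd1, Znrf3 and Notum had ratios of 0.623, 0.656 and 0.288, in contrast to the R-spondin receptor Lgr5, at 3.12 (2.22 to 4.58), and Ccnd1, at 1.11. Homeostasis genes had a median of −0.26 (−0.43 to 0.01), with 9 of 12 lower. Glutamine synthetase (Glul), which detoxifies transmitter glutamate, stood at 7982 and 6563 CPM, the retinoid carrier Rlbp1 at 3926 and 3246 CPM, and carbonic anhydrase 2 (Car2) at 2179 and 1408 CPM, while the water channel Aqp4 and the glutamate transporter Slc1a3 had ratios of 1.06 and 1.01. The Norrin receptor complex list had a median of −0.33 with 5 of 6 lower, including Lrp5 (0.767, 0.613 to 0.955) and Tspan12 (0.689), but Ndp was higher (1.53, 1.34 to 1.76). Stress and injury genes had a median of 0.69 (−0.25 to 2.20) with 8 of 11 higher, led by the injury-induced factor Atf3 at 114 and 558 CPM. Oxidative phosphorylation genes (median 0.11, 14 of 18 higher) and immediate-early genes (0.07, 9 of 16 higher) differed little, with Fos at a ratio of 0.874 and Jun at 1.11.

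Beyond the lists, genes named by size that were higher in the KO library included Areg, an EGF-receptor ligand, at 64.2 (8.19 to 1928) from 0.0516 CPM in WT. The phospholipid-binding annexin Anxa2, the prostaglandin F receptor Ptgfr and the collagen-binding endocytic receptor Mrc2 had ratios of 19.6, 16.1 and 22.9, and the scaffold gene Ahnak2 one of 22.1. The interferon-inducible Ifi203, whose reads are shared with close paralogs, had a ratio of 88.9 that rests on 11 KO cells. Lower in the KO library were Slco1c1, the transporter of thyroxine and organic anions, at 23.1 CPM in WT and 0.867 in KO (26.7-fold, 15.0 to 49.2), and Gfra2, the neurturin co-receptor, at 32.0 and 3.21 CPM (9.95-fold, 7.34 to 13.7). The lysophosphatidic acid receptor Lpar3 was lower by 16.9-fold (5.88 to 59.8), the bHLH factor Tfap4 by 11.6-fold, the protease Dpp4 by 7.65-fold, the Ras activator Rasgrp3 by 7.61-fold and Pebp4 by 8.98-fold. The histone genes Hist1h2br and H1f5, whose reads can be shared within their families, were lower by 9.70-fold and 8.12-fold. Mgp, Crip3 and Rgs5 were lower by 28.0-fold, 10.5-fold and 9.73-fold, but 5 WT cells held 90.4%, 99.0% and 79.2% of their WT reads, and Mgp and Rgs5 are vessel-wall transcripts.

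**Figure D2:**
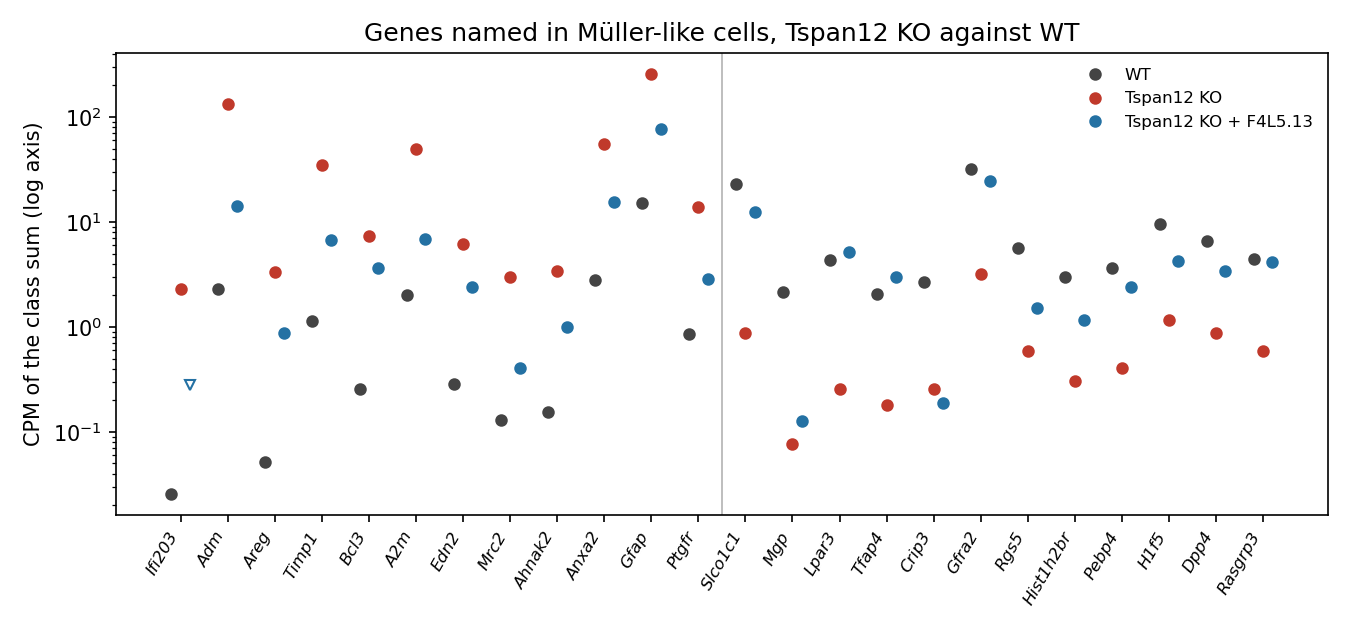
CPM in Müller cells of the WT, KO and treated libraries (log axis) for the 12 highest and 12 lowest genes of the KO against WT comparison. Symbols for 0 reads sit at the limit of 3 counts; Adm reads 2.27, 132 and 14.1 CPM, and Slco1c1 23.1, 0.867 and 12.5 CPM.

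The treated and untreated KO libraries were compared in Müller cells to describe glia of the same labelled genotype with and without the FZD4 and LRP5 agonist. Most transcripts that had been higher in the KO library were lower in the treated one, and most that had been lower were higher, as were 7 of 11 β-catenin targets. Gliosis, hypoxia and interferon genes were the lists furthest below the KO level. Immediate-early genes were slightly higher.

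Gliosis genes had a median of −0.84 (−1.50 to −0.34) with 19 of 22 lower. The iron-binding acute-phase protein Lcn2 stood at 120.1 CPM in KO and 22.6 in treated (ratio 0.188, 0.163 to 0.215), and A2m at 49.1 and 6.85 CPM (0.140). Socs3, Cebpd and Ednrb were instead higher, by ratios of 2.10, 1.45 and 1.56. Hypoxia-response genes had a median of −0.47 (−0.96 to −0.23) with 22 of 27 lower. Adm stood at 132 and 14.1 CPM, a 9.35-fold difference (7.92 to 11.1), Egln3 at 11.1 and 2.92 CPM, and Eno1, the glycolytic enolase, at 2520.5 and 1026 CPM, whereas Ndrg1, also induced by low oxygen, was higher at 1.40 (1.26 to 1.55). All 14 interferon-response genes were lower (median −1.01, −1.29 to −0.54). Ifit1 had a ratio of 0.386, Rtp4 of 0.277 and the ubiquitin-like modifier Isg15 of 0.484.

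The β-catenin targets had a median of 0.54 (−0.14 to 1.56), with 7 of 11 higher, and of 0.00 to 0.62 over the alternative settings. Lef1 stood at 3.03 CPM in KO and 8.95 in treated (ratio 2.95, 2.07 to 4.36), Nkd1 at 110.0 and 181 CPM (1.65, 1.54 to 1.76), Znrf3 at 76.7 and 111 CPM (1.45) and Notum at 0.357 and 2.10 CPM (5.90, 2.31 to 20.9). Lgr5 was lower at 0.252 (0.159 to 0.392). In the Norrin receptor list (median 0.10, 3 higher and 3 lower) Lrp5 was higher at 1.61 (1.29 to 2.02) and Ndp lower at 0.777 (0.675 to 0.892). Homeostasis genes had a median of 0.04 with 8 of 12 higher: the thyroid hormone deiodinase Dio2 and the transporter Abca8a were higher at 1.48 and 1.45, and Aqp4 lower at 0.716. Stress genes had a median of 0.32 (9 of 12 higher), although Atf3 was lower at 0.467, the translational stress factor Atf5 was higher at 1.88 and the glutathione-degrading Chac1 at 5.75. Immediate-early genes had a median of 0.20 (0.03 to 0.53) with 13 of 16 higher, such as Junb and Dusp1 at 1.44 and 1.55. Oxidative phosphorylation genes had a median of −0.15 (15 of 18 lower).

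Among genes named by size, Adamts13, the protease that cleaves von Willebrand factor (chromosome 2, 26973361 to 27009625), had 0 reads in Müller cells of the WT and KO libraries and 11.97 CPM in 147 treated cells, at least 58.2-fold higher than in KO. Genes that were low in the KO library were higher: Lpar3 was 20.1-fold higher than in KO (6.86 to 70.6), Tfap4 16.7-fold, Slco1c1 14.5-fold (7.94 to 27.0), Gfra2 7.64-fold (5.57 to 10.6) and Rasgrp3 7.07-fold. Against WT, Slco1c1 stayed lower at a ratio of 0.542 (0.440 to 0.663) and Gfra2 at 0.768, while the intervals for Lpar3, Tfap4 and Rasgrp3 include 1. The zinc and manganese importer Slc39a8 (7.13-fold), the growth factor inhibitor Wfikkn2 (4.83-fold), the meiotic gene Hormad2 (5.21-fold) and Lef1os1, antisense to Lef1 (5.04-fold), were also higher. Vgf was 14.3-fold higher, but 5 treated cells held 94.8% of its reads. Lower in the treated library were Apln, the endothelial growth peptide apelin, at 117 CPM in KO and 8.61 in treated (13.6-fold, 11.02 to 16.9), and Ndufa4l2, a HIF-induced subunit-like protein of the respiratory chain, at 1491 and 170.4 CPM (8.75-fold, 8.34 to 9.18). Kit ligand (Kitl) was lower by 34.9-fold (7.93 to 249), the cadherin Cdh23 by 17.0-fold (9.48 to 33.0), the phosphatase Ptprr by 9.80-fold, the immune checkpoint gene Vsir by 13.5-fold, and Slc32a1, an amacrine marker, by 9.74-fold. Ifi203 was at least 8.26-fold lower. Fbln1, Ecrg4 and Mia were lower by 44.2-fold, 19.2-fold and 19.4-fold, but 5 KO cells held 100%, 94.1% and 99.0% of their reads.

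**Figure D3:**
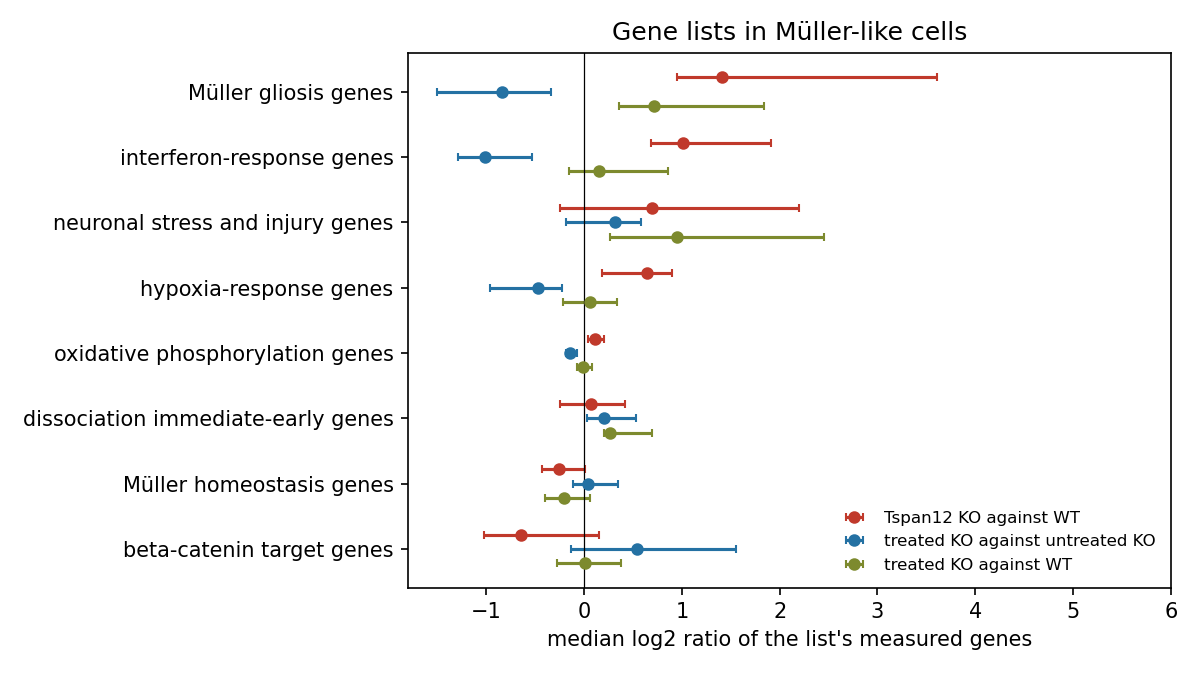
Median log2 ratio of 8 gene lists in Müller cells for the 3 comparisons, with order-statistic 95% intervals over member genes. Gliosis genes lie at 1.41 for KO against WT, −0.84 for treated against KO and 0.72 for treated against WT.

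How far the treated Müller cells lay from WT was examined by a direct comparison and by following the genes that differed in the KO. The hypoxia, interferon and β-catenin lists stood close to WT, while gliosis and stress genes stayed above it. Genes chosen on one random part of the KO cells and measured against the rest mostly differed in the direction of WT. Of 253 genes higher in KO, with a median log2 ratio of 1.47, 95.3% were lower in treated cells than in the remaining KO cells. Their median against WT in the treated library was 0.66 (0.61 to 0.76). Of 156 genes lower in KO (median −1.44), 96.2% were higher in treated cells, with a median against WT of −0.36 (−0.43 to −0.28). These percentages count direction only, so a gene that passed beyond its WT level is included. Simulated treated libraries without any difference from KO gave 47.4% and 39.1%. Across 10926 genes, which are not independent replicates, the KO and treated differences had a covariance of 0.123 and a correlation of 0.76. These were 0.113 and 0.65 when KO cells were divided so that no KO count was shared. An undivided simulation with shared counting error alone gave 0.0104 and 0.47. All KO cells came from 1 library, so a difference private to that library would also place treated cells closer to WT. Neither the division nor the simulation can separate that from an effect of treatment.

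Against WT, the medians were 0.06 (−0.21 to 0.34) for hypoxia genes, 0.15 (−0.16 to 0.86) for interferon genes, 0.00 for β-catenin targets, 0.08 for the Norrin receptor list and −0.01 for oxidative phosphorylation. Gliosis genes remained at 0.72 (0.35 to 1.84), with 21 of 22 higher, and stress genes at 0.95 (0.26 to 2.46), with 10 of 11 higher. Homeostasis genes had a median of −0.21, 8 of 12 lower, and immediate-early genes one of 0.26 (0.20 to 0.69), 14 of 16 higher. Gfap stood 5.04-fold above WT (4.35 to 5.89), Timp1 5.86-fold, Adm 6.19-fold, Anxa2 5.55-fold and Bcl3 14.2-fold (4.87 to 51.8). The amino acid response gene Asns (5.51-fold) and the stress cytokine Gdf15 (8.39 CPM in WT, 12.8 in KO and 38.0 in treated) were higher in the treated library than in both others. The tubulin Tubb6 (7.43-fold), the actin cross-linker Flnc (5.35-fold), the repressor Zfp488 (4.41-fold), Vgf (15.7-fold) and Adamts13 (at least 58.0-fold) completed the higher genes. Most of the 12 lower genes rested on few cells: 5 cells held 97.0%, 97.1% and 99.2% of the WT reads of Fbln1, Optc and Crhbp, which were lower by 49.5-fold, 11.2-fold and 9.80-fold. Mgp, Crip3, Mia, Ecrg4, Ltbp2, Mfap4, Fam129a and Vcan were lower by 3.96-fold to 17.1-fold with 5 cells holding 74.1% or more of their WT reads, and Rbp7, a retinol-binding protein, by 3.90-fold (1.68 to 10.2) from 34 WT cells.

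In endothelial cells only the treated and WT libraries could be compared (17 and 105 cells), because no KO cell was so named, and the question was how close treated vessels lay to WT vessels. The barrier list had more members lower than higher, although Cldn5 was near its WT level and Slc2a1 above it. The β-catenin targets were near WT, and immediate-early genes were higher. With 17 treated cells, 5 of which held 60.4% or more of the reads of each of the 12 named higher genes, single-gene values carry little weight.

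The barrier list had a median of −0.29 (−0.88 to 0.20) with 14 of 22 lower (percentile 0.0100). Claudin-5 (Cldn5) was 6085 and 6049 CPM in WT and treated (ratio 0.994, 0.951 to 1.04), the glucose transporter Slc2a1 had a ratio of 1.28 and the amino acid transporter subunit Slc3a2 one of 1.37. The thyroxine transporter Slco1c1 stood at 577 and 149.8 CPM (0.260, 0.196 to 0.342), the transferrin receptor Tfrc at 206 and 58.6 CPM (0.285) and the glutamine transporter Slc38a5 at 173 and 86.6 CPM (0.501). β-catenin targets had a median of −0.05 (−0.51 to 0.21; 8 of 15 lower), with ratios of 1.15 for Lef1, 1.42 for Axin2 (0.911 to 2.17), 1.15 for Sox17, 1.27 for Foxq1 and 0.703 for Apcdd1. Arterial genes (median 0.11, 6 of 11 higher) included the connexin Gja4 at 1.88 and the kinase Bmx at 2.97, and venous genes (−0.04, 4 of 8 higher) included Nr2f2 at 0.892. Basement membrane genes had a median of −0.01 (6 of 12 higher; Col4a1 at 1.16), tip-cell genes one of −0.27 (8 of 12 lower, although the Notch ligand Dll4 was at 1.79), which became 0.40 to 0.51 under 4 alternatives, and fenestration and activation genes one of 0.00 (5 of 9 higher; Vwf at 0.905). Proliferation genes (−0.10, 4 of 8 higher), hypoxia genes (−0.00, 13 of 25 lower), oxidative phosphorylation (−0.07, 13 of 18 lower), stress genes (0.23, 6 of 9 higher) and the Norrin receptor list (0.09, 3 of 5 higher) gave no list-wide direction. Interferon genes were lower (−0.33, −0.61 to −0.12; 12 of 14), for example Ifit1 at 0.642, and immediate-early genes higher (0.67, 0.15 to 0.98; 14 of 16), such as Fos at 1.85 and Zfp36 at 2.25.

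The endothelial genes named by size as higher in the treated library were the metalloreductase Steap4 (5.61-fold, 3.50 to 9.25), the AP-1 member Fosl2 (4.18-fold, 3.03 to 5.65), the alkaline ceramidase Acer2 (3.27-fold), Atf3 (2.88-fold), Socs3 (2.77-fold), the calcium-binding S100a6 (3.47-fold), the EGF-receptor inhibitor Errfi1 (2.65-fold), the metalloproteinase Adamts1 (2.61-fold), the YAP target Ccn2 (2.61-fold), the homeobox gene Hhex (2.48-fold), Sbno2 (2.46-fold) and Arhgap20 (2.65-fold). Lower were the vitamin A receptor Stra6, at 173 and 16.8 CPM (10.3-fold, 4.80 to 28.8), the monoacylglycerol lipase Mgll (7.03-fold, 3.07 to 18.5), the transmembrane protein Islr2 at 112 and 0.931 CPM (120.4-fold, at 1 treated read, with a lower bound of 11.02), the ATPase Atp13a5 (10.7-fold, 2.46 to 75.5) and the endocytic receptor Ly75 (6.57-fold, 1.504 to 47.0). Kctd10 and Emc9 were at least 3.16-fold and 2.97-fold lower. The neuronal transcripts Chgb and Ret were at least 2.48-fold and 2.28-fold lower, Stmn2 8.13-fold and Calb1 9.98-fold, the last from 12 WT cells.

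Bipolar cells were compared as the most numerous neurons other than photoreceptors, and some of their clusters were uneven between libraries, one holding 29 WT, 245 KO and 16 treated cells. The KO library had higher hypoxia-response, interferon and immediate-early transcripts than WT, and the treated library had lower ones than KO, while the list of ON-bipolar signalling genes had medians near 0 in both comparisons. Hypoxia-response genes had a median of 0.89 (0.58 to 1.15) for KO against WT, with 25 of 26 higher, and −0.74 (−1.28 to −0.44) for treated against KO, with 25 of 25 lower. Lactate dehydrogenase (Ldha) stood at 703 CPM in WT, 1226 in KO and 694 in treated, triosephosphate isomerase (Tpi1) at 1730.4, 2626 and 1697 CPM, and Egln3 at 0.0253, 8.10 and 0.286 CPM, a KO to WT ratio of 320.1 with a lower bound of 32.0. Interferon genes had medians of 0.66 (10 of 12 higher) and −0.65 (11 of 12 lower), and immediate-early genes 0.54 (0.32 to 0.91; 15 of 16 higher) and −0.46 (−0.90 to −0.18; 13 of 16 lower), with Egr1 at 186, 471 and 252 CPM. ON-bipolar genes had medians of 0.04 and −0.02, and Trpm1, the transduction channel, ratios of 1.12 and 1.02. Stress genes (0.49 and −0.32), oxidative phosphorylation (−0.08 and 0.03) and β-catenin targets (−0.07 and 0.07) completed the lists.

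Among bipolar genes named by size, the intermediate filament peripherin (Prph) had 0 reads in WT and 11.6 CPM in KO, at least 57.4-fold higher. Serpina3n, the acute-phase inhibitor, Il27 and the matricellular Postn had ratios of 268, 239 and 105 with lower bounds of 26.5, 23.7 and 13.5. Serpina3n is also on the Müller gliosis list and a leading gene of an astrocyte cluster with 2 WT, 23 KO and 8 treated cells. Lower in KO were Gfra3, the artemin co-receptor (5.01, 0.438 and 5.18 CPM over the 3 libraries; 11.4-fold), Adamtsl3 (10.9-fold), AW822252 (19.6-fold), the monooxygenase Fmo2 (at least 11.6-fold) and Cldn5 (at least 10.6-fold). Cldn5 is an endothelial gene: in barcodes with fewer than 3 endothelial markers of any class it stood at 2.31, 0.0159 and 0.561 CPM, the order of the endothelial shares. The summed endothelial markers did not follow that order in the same barcodes, at 339, 302 and 262 CPM in WT, KO and treated. In the treated library Adamts13 (at least 22.7-fold), Gfra3 (11.8-fold), the choline-transporter-like Slc44a3 (10.2-fold), Hamp2 (9.35-fold) and, from 6 cells, Spp1 (17.1-fold) were higher than in KO. Lower were the MHC class II chain H2-Ab1 (0.329, 21.2 and 0.599 CPM; 35.5-fold, 17.3 to 81.3), the synaptic organisers Nxph4 (35.3-fold) and C1ql2, an amacrine marker (34.3-fold), Postn (102-fold) and Egln3 (28.3-fold).

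**Figure D4:**
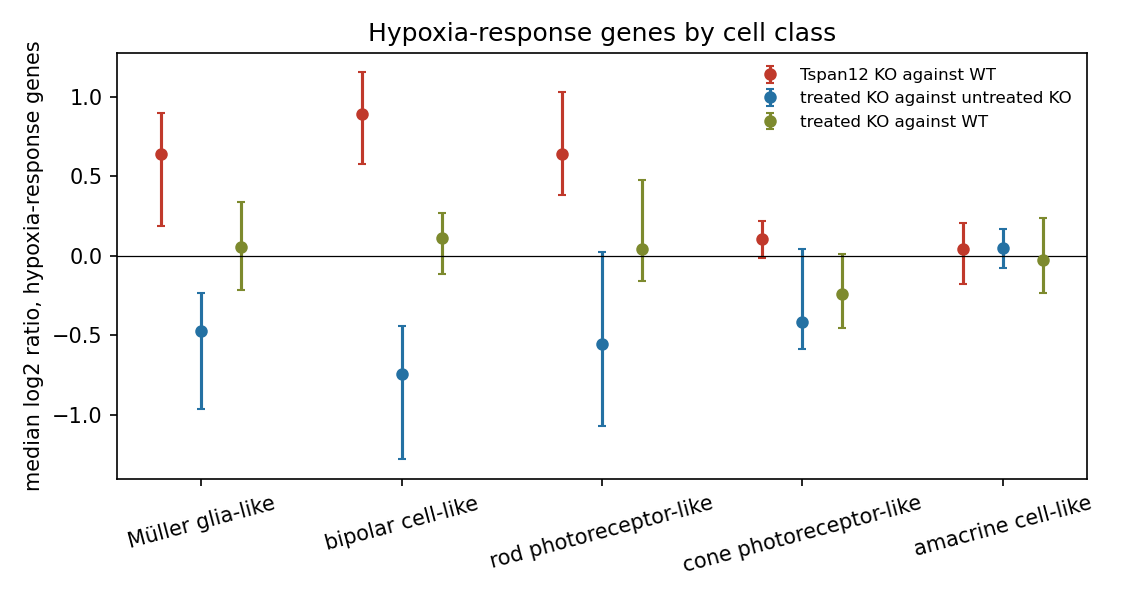
Median log2 ratio of the hypoxia-response list in 5 classes, with order-statistic 95% intervals over member genes, for KO against WT, treated against KO and treated against WT. For KO against WT and treated against KO, bipolar cells lie at 0.89 and −0.74, Müller cells at 0.64 and −0.47, and amacrine cells at 0.04 and 0.05.

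In rods, cones and amacrine cells the same 2 comparisons differed by class. Hypoxia genes in rods were higher in KO by an amount that depended on the scaling, in amacrine cells they had a median near 0, and in cones they were lower in treated than in KO but near 0 for KO against WT, a value that differed between settings (−0.13 to 0.83). In rods the scaling matters: the median of all genes was 0.43 for KO against WT and became 0.06 with TMM and 0.02 with DESeq2 factors, and the 258 WT rods had a median of 16392 reads and the 3762 KO rods 3127. The rods also lay in different clusters, with 159 and 45 WT cells in a pair of clusters that held 57 and 1 KO cells. Rod hypoxia genes had medians of 0.64 (0.38 to 1.03; 21 of 24 higher) and −0.55 (−1.07 to 0.02; 17 of 24 lower), and the first was 0.27 with TMM and 0.22 (−0.03 to 0.61) with DESeq2. Immediate-early genes in rods had medians of 0.94 and 0.22, interferon genes 1.49 and −0.33, stress genes 0.84 and −0.29, oxidative phosphorylation −0.19 and −0.12, and β-catenin targets 0.18 and −0.39. Rph3a, Bcl3, Lamp5, Camkv and Cartpt, of which Rph3a is a synaptic vesicle effector, had 0 reads in WT rods and were at least 6.46-fold to 8.39-fold higher in KO. Lamp5 and Cartpt are also leading genes of amacrine clusters, a class with 118 cells in WT and 1214 in KO. The potassium channel subunit Kcne2 stood at 92.9, 2.30 and 16.9 CPM (40.4-fold lower in KO, 21.6 to 76.5) and the β1 adrenoceptor Adrb1 at 75.9, 4.75 and 12.1 CPM (16.0-fold lower), with Fzd10 and Pgc lower by 28.5-fold and 21.5-fold and Agr2 by 223-fold at 1 KO read, with a lower bound of 21.3. Kcne2, Agr2 and Fzd10 are leading genes of cone clusters, and the rod cluster with 45 WT cells and 1 KO cell carried all 9 cone markers as well. In treated rods Adamts13 (at least 13.5-fold), Kcne2 (7.34-fold), the homeodomain-only gene Hopx (4.46-fold), Nptx1 (4.36-fold) and Frs3 (3.71-fold) were higher than in KO. The glycolytic regulator Pfkfb3 (15.9-fold, 4.64 to 72.5), Ebf1 (14.8-fold), Vsnl1 (11.6-fold), Pcdh17 (9.15-fold) and Lamp5 (9.05-fold) were lower.

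Cone hypoxia genes had medians of 0.11 (−0.01 to 0.22; 16 of 23 higher) and −0.41 (−0.59 to 0.05; 16 of 23 lower). Cone interferon genes had medians of 0.89 and −0.63, immediate-early genes 0.14 and 0.46, stress genes 0.26 and 0.09, oxidative phosphorylation −0.10 and 0.14, and β-catenin targets −0.06 and 0.31. Irf7, the master regulator of the interferon response, stood at 4.74, 35.0 and 4.51 CPM in cones, the endothelin receptor Ednrb at 1.84, 22.8 and 2.52 CPM, and the guidance gene Slit2 at 5.62, 45.0 and 3.45 CPM, with Syt4 and Kcnc1 also higher in KO (7.13-fold and 6.07-fold). Slit2 is a leading gene of bipolar clusters too, and 5 cells held 84.5%, 58.2% and 92.3% of its cone reads. Lower in KO cones were Gpr61 (8.53-fold), Tbc1d22bos (7.79-fold), the opsin-like Rrh (5.03-fold, 1.76 to 28.6), Sprn (3.84-fold) and Rnf5 (2.77-fold). All KO reads of Rrh came from 5 cells, and its log2 ratio was of opposite sign, 2.52 and 2.68, under 2 other clusterings. Treated cones had more Hopx (91.3, 43.3 and 238 CPM; 5.49-fold), the antiviral Zc3hav1 (7.46-fold), Ankrd2 (7.35-fold), Espl1 (4.92-fold) and Abcc8 (4.82-fold) than KO cones, and less Ntng1 (13.7-fold, with 76.6% of KO reads in 5 cells), Slit2 (13.1-fold), Dnaic1 (9.66-fold) and Snhg11 (9.14-fold).

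Amacrine hypoxia genes had medians of 0.04 (−0.18 to 0.21; 17 of 26 higher) and 0.05 (15 of 26 higher). Their immediate-early genes had medians of −0.69 (−1.13 to 0.19; 12 of 16 lower) and 0.12, interferon genes 0.23 and −0.66, stress genes 0.06 and −0.39, oxidative phosphorylation 0.13 and −0.12, and β-catenin targets −0.20 and 0.07. KO amacrine cells lay partly in clusters nearly empty in the other libraries, one holding 2 WT, 184 KO and 4 treated cells, so these medians and the genes named by size compare different clusters. The neuropeptides Vip (0.991, 137 and 1.06 CPM), Tac2 (0, 62.3 and 55.4 CPM) and Npy (1.98, 204 and 177 CPM) and the glutamate transporter Slc17a8 (at least 4.04-fold) were higher in KO, as was Shb (at least 3.15-fold). Sst, at 691 CPM in WT, came from 1 WT cell. The myogenic factor Myf6, known from subsets of amacrine cells, was 36.4-fold lower in KO, and Id3, Hes5 and Id1, each with 92.5% or more of WT reads in 5 cells, were lower by 19.6-fold, 19.5-fold and 14.3-fold. Against KO, the treated library had more Sct, Nr2e3, Tll1, AI847159 and Cngb1 (4.06-fold, 3.94-fold, 3.87-fold, 3.82-fold and 3.35-fold), of which Nr2e3 and Cngb1 are rod genes, and less Gsg1, Trp53i11 and Bean1 (at least 7.29-fold, 3.14-fold and 2.94-fold) and Vip (129-fold).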

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

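No paired analysis was possible because each group has 1 library, and leaving out a replicate was not possible for the same reason. Settings were altered one at a time; the most evenly shared cluster, the marker-based endothelial barcodes and the inclusion of the cluster with endothelial markers and haemoglobin were chosen after seeing the data. Of the values that describe whole comparisons, 689 stayed and 58 moved, some of them to the opposite sign where the main interval included 0. Of single-gene values, 10112 stayed, 1142 moved and 14 took the opposite sign with both intervals excluding 0. Other changes of sign, where an interval included 0, are counted among the values that stayed or moved. The proportion of gene values with the same direction was lowest, 83.9%, for endothelial barcodes picked by markers and 84.8% in the most evenly shared cluster. Over all settings the Müller medians for KO against WT ran from 1.34 to 1.46 for gliosis, 0.52 to 0.70 for hypoxia and 0.90 to 1.11 for interferon genes, but −0.74 to 0.02 for β-catenin targets. For treated against KO they ran from −0.90 to −0.70, −0.73 to −0.43, −1.14 to −0.84 and 0.00 to 0.62. The all-gene medians in rods and cones, KO against WT, were 0.43 and 0.09, and became 0.06 and −0.04 with TMM and 0.02 and −0.02 with DESeq2. Where a value moved, the cause was not tested. A log-scale alternative was not run because the tables hold counts, free RNA was not subtracted in rods, which were its source, and the planned endothelial comparisons with KO gave no value.

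In the most evenly shared cluster, log2 ratios were −0.20 for Cebpd (Müller, KO against WT), −0.13 for Ndufa4 (Müller, treated against WT), −0.35 for Btg2 (bipolar, KO against WT) and 0.0942 for Tpi1 (bipolar, treated against WT; otherwise −0.0282), and the bipolar immediate-early median for KO against WT was 0.96. With a gene minimum 2 times the main one, Müller Ndufa4 (KO against WT) was 0.23 and Vim (treated against KO) 0.0453, the KO shares were 30.4% Müller and 23.9% amacrine, the WT bipolar share was 59.2%, and no cluster was named endothelial, so that share was 0% in WT and treated. With at least 200 genes, the endothelial tip-cell median was 0.40, the KO amacrine share 25.2% and the endothelial share 0.114% in KO and 0.975% in treated. A mitochondrial limit of 10% gave 1.77% endothelial cells in WT. With doublets kept, Müller Glul and Jun (treated against KO) were −0.0210 and −0.0358, cone Nnat (treated against WT; otherwise −1.97) 0.39, cone hypoxia (KO against WT) 0.29 and the tip-cell median 0.51. Müller shares were then 38.3%, 30.8% and 33.6% in WT, KO and treated, bipolar shares 54.4%, 37.9% and 57.8%, and endothelial shares 0.120% in KO and 1.01% in treated.

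Clustering at resolution 0.5 gave cone Rrh 2.52 and cone hypoxia medians of 0.68 (KO against WT) and −1.16 (treated against KO), with Müller shares of 25.9% and 28.1% and bipolar shares of 41.3% and 63.0% in KO and treated. Resolution 2.0 gave 24.9% amacrine cells in KO and endothelial shares of 1.67%, 0.113% and 0.242% in WT, KO and treated. Clustering each library on its own gave cone Rrh 2.68, cone hypoxia 0.83 and −1.06, amacrine hypoxia (treated against KO) −0.12, KO shares of 29.8% Müller, 21.3% amacrine and 43.5% bipolar, and endothelial shares of 0% in WT and 1.24% in treated. Subtracting free RNA gave −0.65 for Müller Ldha (treated against WT) and −0.13 for cone hypoxia (KO against WT). The mean over cells gave 0.000358 for Müller Vim and −0.0132 for bipolar Trpm1 (both treated against KO). With TMM, hypoxia medians for KO against WT were −0.0192 in cones and 0.27 in rods, and 0.22 in rods with DESeq2. One random part of the cells gave −0.16 for amacrine hypoxia (treated against KO). Endothelial barcodes with 8 markers gave a tip-cell median of 0.47. With the haemoglobin-bearing cluster it was 0.40, and the endothelial share was 0.132% in KO and 0.992% in treated. At a ratio of 1.5, the treated against WT medians were 0.41 for genes higher and −0.20 for genes lower in KO. Of the 24 named genes, a minimum of 10 molecule equivalents left 9 (Müller, KO against WT), 7 (treated against WT), 10 (treated against KO) and 14 (endothelial) in common, and a minimum of 100 left 10, 10, 11 and 8.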

Other observations

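A few genes were higher or lower in the same direction in all 5 classes that could be compared. Free RNA was estimated only for rod transcripts, so how much of these differences reached each class as RNA from another class is not known. Higher in the KO library by at least 2-fold in every class were 4 genes: the metallothioneins Mt1 and Mt2, which bind zinc and copper, the microtubule regulator Stmn4, and Mif-ps, a pseudogene whose reads are not separable from Mif. In Müller cells Mt1 stood at 1839, 7905 and 3170 CPM and Mt2 at 258, 1466 and 474 CPM in the WT, KO and treated libraries, and in bipolar cells Mt1 stood at 618, 2181 and 654 CPM. In the treated library 5 genes were lower than in KO in every class: Mt1, Mt2, Mif-ps, the X-linked Xlr3a, and Ndufa4l2. Ndufa4l2 stood at 99.4, 1491 and 170.4 CPM in Müller cells, 3.83, 37.1 and 4.96 CPM in rods and 3.78, 20.9 and 2.92 CPM in cones, so like Mt1 and Mt2 it was far more abundant in Müller cells than in photoreceptors. Adamts13 was the only gene higher in every treated class, with 0 reads in all 5 KO classes and 0.0759 CPM in WT bipolar cells. C57BL/6 mice are known to carry a retroviral insertion that truncates the 3′ end of Adamts13, and whether the 3 groups shared a strain is not given in the sources used here.

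Signs of contact with vessels and of contamination by other cells were looked at beside these. Barcodes with endothelial markers often carried 3 or more mural markers as well: 94 of 116 in WT (81.0%) and 31 of 37 in treated (83.8%), but 1 of 6 in KO (16.7%), the haemoglobin-bearing cluster included. The KO barcodes were far shallower, with a median of 4479 reads against 65607.5 in WT and 52575 in treated. Rod markers made up 1.19%, 0.897% and 1.16% of Müller reads and 0.252%, 0.133% and 0.155% of bipolar reads. Free RNA was estimated at 12.5%, 14.4% and 16.7% of Müller reads, 2.66%, 2.13% and 2.24% of bipolar reads and 23.3%, 19.9% and 24.7% of cone reads.

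Thinning of reads was chosen before the data were examined, and the other tests of the 3 patterns that follow were chosen only after the results were seen. Hypoxia-response genes were higher in the KO library and lower in the treated one in Müller and bipolar cells. In the most evenly shared Müller cluster the KO against WT median was 0.55 (0.29 to 0.89), which argues against cluster makeup. With cells thinned to 5000 reads it was 0.69 (0.32 to 0.88), so the value did not rest on the greater weight of deep cells. Thinning leaves the expected proportions within each cell unchanged, so it cannot decide whether the difference goes with depth in other ways. Handling stress would need immediate-early genes to follow the same course: in Müller cells they had a median of 0.0714 (−0.25 to 0.41) for KO against WT, which decides nothing, and were higher at 0.20 (0.03 to 0.53) for treated against KO, which argues against it there. In bipolar cells they were higher in KO at 0.54 (0.32 to 0.91), so handling stress may contribute to the bipolar values. A difference between single animals or dissociations stays open, as does low oxygen in a poorly vascularised retina relieved by F4L5.13, which the design names and no test here reached.

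Endothelial cells were nearly absent from the KO library and partly present in the treated one. Among all barcodes, before any filter or naming, 0.0186% of the KO library had at least 8 endothelial markers, and among barcodes of at least 20000 reads 0.0382% did, against 2.13% and 5.67% in WT, which argues against filters, naming and depth. Mural cells were 0.265% (0.137 to 0.463%) in KO and 0.0844% in WT, but most WT endothelial barcodes carried mural markers too, so these values do not decide whether vessels were lost in the preparation, which could give the gap. Fewer endothelial cells in the KO retina, and their return with F4L5.13, remains an open explanation without a test.

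Amacrine cells were far more numerous in the KO library than in either other library. By markers alone, 9.14% (8.60 to 9.70%) of all KO barcodes and 12.1% (11.3 to 12.8%) of those above the WT read minimum were amacrine-like, against 1.12% in WT, which argues against naming and shallow barcodes. Per 100 Müller cells, horizontal cells were higher in KO by 2.58 (1.75 to 3.86) and amacrine cells by 13.4 (11.1 to 16.4), so a loss of Müller and bipolar cells alone does not account for the excess. Microglia were higher by 6.91 (3.87 to 13.2) and ganglion cells, from 2 and 28 cells, by 18.3 (4.61 to 158), and an uneven loss that spared some classes stays open. A different yield of amacrine cells from that dissociation could produce the 13.4-fold gap and cannot be told apart from a KO retina that itself holds more amacrine cells or fewer other neurons, which was not tested.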
